A study of Mus musculus with 6 samples.

How the data were processed

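RNA sequencing was carried out on macrophages sorted from the calf muscle of mice 3 days after hindlimb ischemia, an injury in which the blood supply of the leg is interrupted. Per the labels' protocols, mice received 1 mg of tamoxifen on 5 consecutive days, with at least 7 days before the experiment, between 7000 and 50000 sorted cells were lysed per sample, and libraries were made with a low-input SMARTer kit, which amplifies cDNA before library construction. The genotype label places 3 libraries in the wild-type group (WT) and 3 in the Pfkfb3 knockout group (KO). The design text names endothelial cells (EC), which line blood vessels, beside the gene, and the deletion was taken to be in them. The genotype label names no cell type. The sample titles name macrophages, the profiled cells, and do not say in which cells the gene was deleted. Replicates were numbered 1 to 3 in the order of the sample records, and the labels do not say whether the libraries of a group came from separate animals, so p-values measure the spread between these libraries, part of which may be technical.

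The authors deposited a single table of whole-number read counts per gene, with 1 column per library and 55353 rows, and no other columns of values. Per the submitters' processing notes, the build was GRCm38 and the tools were Trim Galore, FastQC, HISAT2, featureCounts and DESeq, named with no version or role; the annotation and the strand setting are not given in the sources used here. Counts of genes that overlap on opposite strands are therefore uncertain. In 26 rows the gene symbol had been turned into a calendar date by a spreadsheet. These rows held 0.0913% to 0.163% of the counts of a library and were left out of library sizes and of the main tests. All 37 rows of mitochondrially encoded genes were listed at 0 in all 6 libraries, so the gene list of that name had no tested member. Positions were taken from the GENCODE M21 annotation of GRCm38, matched on the symbol, which matched 53435 rows of the table and 14744 of the 14987 tested genes.

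Library totals ranged from 18853712 to 29060584 counts. Counts in protein-coding genes came to 20301700 ± 2971960 (SD, n = 3) in the WT group and 10280800 ± 1855170 (SD, n = 3) in the KO group, so values of low genes were less precise in the KO libraries. Library sizes were scaled with TMM factors, which were 1.23 to 1.26 in the WT libraries and 0.713 to 0.892 in the KO libraries. Levels are given as CPM, counts relative to the scaled library size.

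Changed genes were called with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the group, and the quasi-likelihood test (glmQLFit and glmQLFTest, two-sided) compared KO with WT over all 6 libraries with no covariate. Genes with a Benjamini-Hochberg adjusted p under 0.05 are said to have changed. Adjusted p-values of genes come from this test unless another is named. The 36 gene lists (pathways, macrophage states, technical responses and markers of other cell types) were written before the data were examined. Of these, 32 had at least 5 tested members and were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, which compares the genes of a list with all other genes, with adjustment over the lists. Each list was also tested with a correlation estimated from the data and with fry, a rotation test. Counts of list members are given over all genes tested and adjusted over the list alone.

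Genes were named by a rule fixed before the data were examined. It takes Pfkfb3 in each library. It takes the 10 largest rises and the 10 largest falls among called genes with no overlap between groups, a mean of at least 50 counts and a symbol that is not a gene model name. It takes up to 2 members per direction, by smallest p, from each list that passed its test or held a called gene, and in any case from the pro-inflammatory, reparative, lactate, glycolysis, hypoxia and angiogenic lists. It also takes a fixed set of macrophage genes, namely Arg1, Nos2, Mrc1, Il1b, Tnf, Vegfa, Igf1, Slc16a1, Hif1a, Adgre1 and Ly6c2. The rule gave 125 genes. Genes named outside it are said to have been chosen after their values were seen.

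Alternatives fixed before the data were examined were DESeq2 size factors, library sizes with no scaling factor, no count filter, a stricter filter (CPM of at least 1 in at least 3 libraries), each library left out in turn, the ending of the sample title as a replicate block, DESeq2 1.42.0, limma-voom with sample weights, a test against a fold of 1.5, camera with an estimated correlation, and fry. Alternatives chosen after seeing the data were protein-coding genes alone, libraries thinned to an equal total of protein-coding counts (their total counts still differed), removal of each library's trend with GC content and exonic length (generalized additive model, mgcv 1.9.3), a sex term and leaving out KO replicates 1 and 2 (both of which leave the genotype effect to the single library KO replicate 3, assumed to vary like the others), and adding up the counts of KO replicates 1 and 2. Pairs of libraries were compared by chi-square over protein-coding genes with at least 20 counts in the pair.

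The procedure was tested on simulated data for this comparison. Counts were drawn for 14987 genes from the means, spread and scaled library sizes of the table, and 14608 of them passed the count filter. Changes were planted in 200 genes with a mean of at least 50 counts. Each gene was drawn on its own, so correlation between genes, the sex difference and an outlying library were not reproduced. The rates below hold for such data alone. edgeR recovered 56 of the 100 genes changed 2-fold and 99 of the 100 changed 4-fold, and 5.49% of its calls were false. DESeq2 recovered 72 and 100 of them with 16.9% false calls, and limma-voom 53 and 98 with 5.63%.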

Results

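Macrophages were sorted from the calf muscle of mice 3 days after hindlimb ischemia and profiled by RNA sequencing. The comparison asked how the transcriptome of muscle macrophages differs when Pfkfb3, which encodes an enzyme that promotes glycolysis, is deleted, per the design text in endothelial cells. There were 3 libraries from wild-type mice (WT) and 3 from mice labelled as Pfkfb3 knockout (KO). Total counts were 21029637, 29060584 and 27828989 in WT replicates 1 to 3 and 21070130, 19696566 and 18853712 in KO replicates 1 to 3.

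Pfkfb3 (ENSMUSG00000026773, chromosome 2, 11471433 to 11554077, GRCm38) was measured at 70.9, 101 and 82.4 CPM in WT replicates 1 to 3 and at 55.5, 59.3 and 160 CPM in KO replicates 1 to 3. The group means were 84.7 ± 15.2 CPM in WT and 91.7 ± 59.3 CPM in KO (SD, n = 3 each), a log2 fold change of 0.11 with an adjusted p of 0.89. With limma-voom and sample weights the log2 fold change was -0.65 (adjusted p = 0.015), and with a sex term it was 0.92 (adjusted p = 0.030), a value that rests on KO replicate 3 alone. Over 20 alternatives the adjusted p ranged from 0.015 to 1.00. Without KO replicate 3 the log2 fold change was -0.56 (adjusted p = 0.066). The design text names endothelial cells (EC) beside the gene, while the genotype label names no cell type. The sample titles name macrophages and do not say in which cells the gene was deleted. If the deletion is endothelial, the level of Pfkfb3 in sorted macrophages checks nothing about the genotype labels.

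The libraries also differed in ways other than genotype. Xist, the RNA that silences an X chromosome in females, was at 154 and 171 CPM in KO replicates 1 and 2, at 0.13 CPM in KO replicate 3 and at no more than 0.47 CPM in the WT libraries. Ddx3y, a Y-linked gene, was at 63.9 CPM in KO replicate 3, at 60.5 to 69.2 CPM in the WT libraries and at no more than 0.53 CPM in KO replicates 1 and 2. Counts of KO replicates 1 and 2 differed from each other by a chi-square of 3.87 per degree of freedom over 11436 genes, which is above sampling noise, against 29.3 to 116 for all other pairs of libraries. Other measures set this pair apart by little or not at all. Its Pearson correlation of log2 CPM was 0.981, against 0.986 for WT replicates 2 and 3. Its Spearman correlation was the highest of all pairs, at 0.988, against 0.987 for those WT libraries. Over low-count genes its chi-square per degree of freedom was the lowest of all pairs, at 2.34, against 2.82 for those WT libraries. KO replicates 1 and 2 were kept as separate samples. Since KO replicates 1 and 2 are the only libraries of their sex type, a fit with a sex term and a fit with both left out each compare the single library KO replicate 3 with WT. They count as 1 comparison, and assume that this library varies like the others. A group of 6 rows, led by the small RNA model Gm23935, took 46.9% ± 6.43 of the counts in KO and 18.9% ± 2.06 in WT (SD, n = 3 each; exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries allow). The share was 16.8% to 20.9% in the WT libraries and 39.7% to 51.8% in the KO libraries. This difference, which may be technical, cannot be told apart from the genotype, and its cause was not tested.

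**Figure D1:**
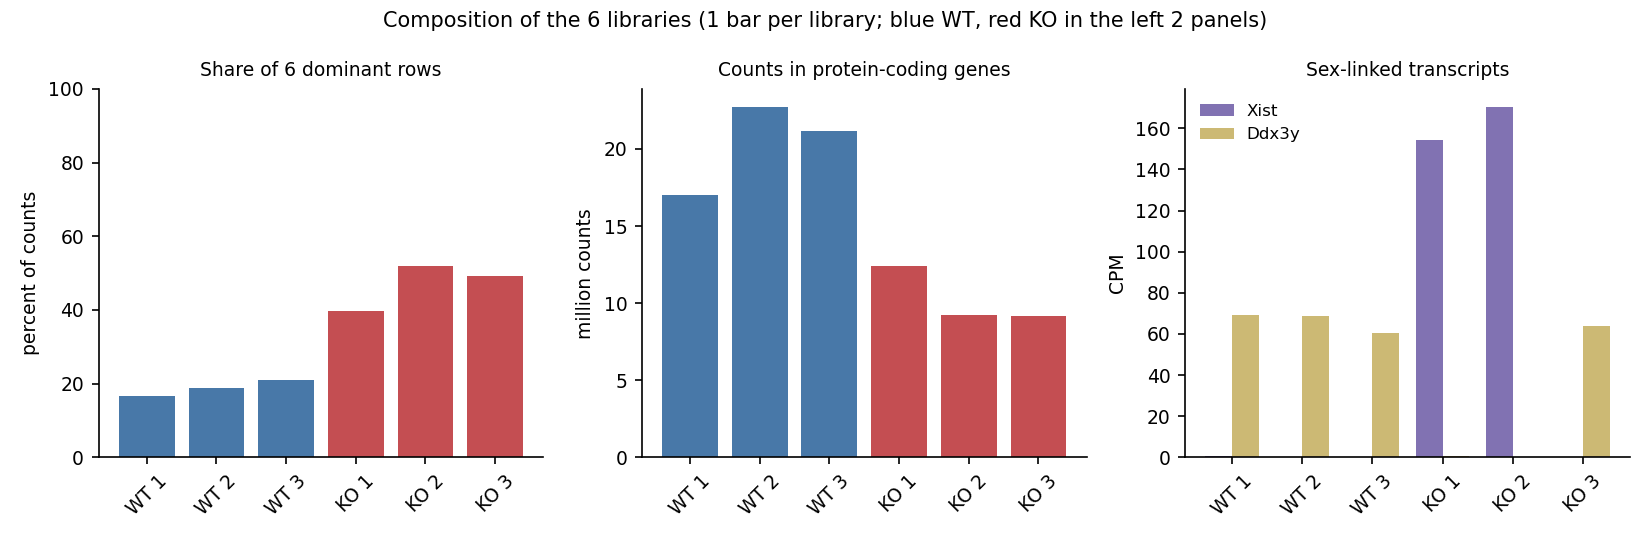
Each bar is 1 library. The left panel gives the percent of counts in 6 dominant rows, the middle panel the counts in protein-coding genes, and the right panel Xist and Ddx3y in CPM. The dominant rows took a mean of 46.9% of the counts in KO and 18.9% in WT, and Xist was high in KO replicates 1 and 2 alone.

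In macrophages from KO muscle, 10 of 25 measured genes of the Ly6C-high monocyte list fell and none rose, and 10 of 24 measured genes of the tissue macrophage list rose and 1 fell. Both lists passed the list test at the preset correlation, with an adjusted p of 0.14 each with an estimated correlation. At the preset correlation, 7 of the 10 splits of the 6 libraries into 3 and 3, the real one included, gave at least as many lists as the real split. A pass at that value is therefore weak evidence by itself. Markers of other cell types moved in the same libraries, with median log2 fold changes of 2.43 in the myoblast list, 1.95 in the fibroblast list, -1.85 in the endothelial list and -1.92 in the neutrophil list. With an estimated correlation their adjusted p was 0.14, 0.20, 0.25 and 0.20. Chil3, a chitinase-like protein of Ly6C-high monocytes, fell from 76.6 ± 13.7 to 4.37 ± 0.865 CPM (SD, n = 3 per group; log2 fold change -4.13, SE 0.21, adjusted p = 8.9e-05). Fn1, which encodes fibronectin and is on the same list, fell from 2873 ± 1251 to 478 ± 83.4 CPM. Of the tissue macrophage list, C1qa and C1qc, subunits of complement C1q, rose from 439 ± 42.5 to 1516 ± 191 CPM and from 366 ± 57.2 to 926 ± 79.3 CPM. Outside these lists, Spp1, which encodes osteopontin, fell from 3522 ± 344 to 916 ± 47.9 CPM. Vcam1, an adhesion molecule, rose from 3.69 ± 0.663 to 43.8 ± 4.82 CPM, and Slc40a1, the iron exporter ferroportin, rose from 2.04 ± 0.518 to 20.3 ± 3.17 CPM. Since Vcam1 is on the satellite cell and myoblast list, its cell of origin in these libraries is not known. The cell of origin of the other named genes was not measured either, since the libraries are bulk RNA and markers of other cell types moved in them. On GRCm38, Chil3 lies on chromosome 3 at 106147554 to 106167564, Fn1 on chromosome 1 at 71585520 to 71653200, C1qa on chromosome 4 at 136895917 to 136898803 and Spp1 on chromosome 5 at 104435118 to 104441050.

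In all, 995 of 14987 tested genes changed (edgeR quasi-likelihood test, adjusted p under 0.05), 658 higher and 337 lower in KO. The groups did not overlap in 31.5% of all tested genes, where chance gives 10%. With library sizes alone, which shifts the median log2 fold change of all genes to -0.60, the split was 300 higher and 6008 lower. The count was 587, 275 and 477 genes without WT replicate 1, 2 and 3, and 293, 189 and 1652 genes without KO replicate 1, 2 and 3. It was 282 genes with KO replicates 1 and 2 added up as 1 sample and 149 genes with both left out. Of all 995 changed genes, 165 kept their call in each of the 6 leave-outs, 136 higher and 29 lower in KO. Of the 75 named genes that changed, many of them picked for large changes or small p-values, 37 did so. Chil3, Fn1, Spp1, C1qa, C1qc, Vcam1 and Slc40a1 were among these 37. The 10 largest falls taken by the naming rule were, in order, Cd177, Chil3, Igfbp3 (log2 fold change -3.42), Cd24a, Ace (-3.03), Rgcc (-2.76), Adgrf5 (-2.63), Ptprb (-2.59), Fn1 and Olr1 (-2.51). Of Igfbp3, Ace, Rgcc, Adgrf5, Ptprb and Olr1, Rgcc alone kept its call in all 6 leave-outs, while Igfbp3 kept it in 1.

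**Figure D2:**
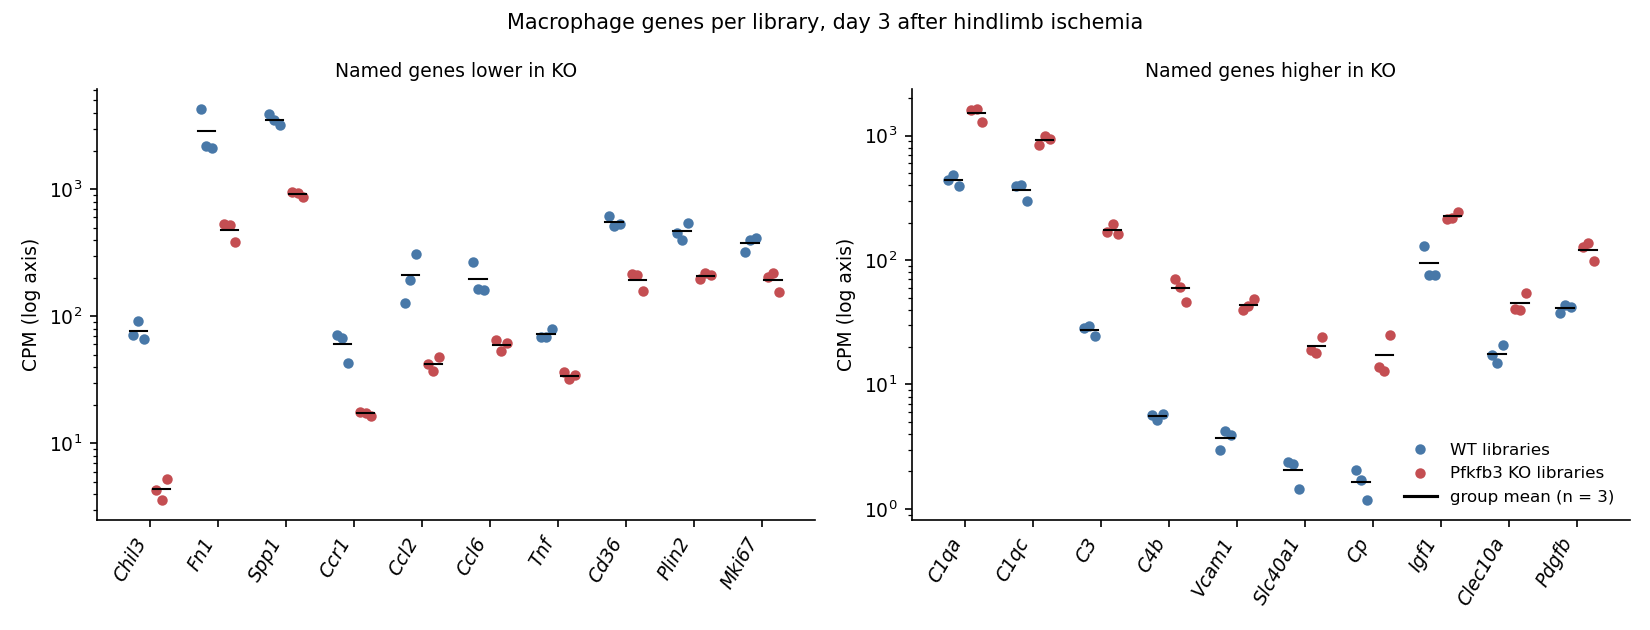
Each point is the CPM of 1 library on a log axis, in blue for WT and red for KO, and each line is a group mean of 3 libraries. The 20 genes were taken from the named genes that changed, so that the separation of the groups in them follows from the choice. Not all are particular to macrophages, and Vcam1 is on the satellite cell and myoblast list. Chil3, for example, was at 3.57 to 5.29 CPM in KO and 66.4 to 92.2 CPM in WT.

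In the Ly6C-high monocyte list 14 of 25 genes fell when adjusted over the list alone, against 10 over all genes, with a median log2 fold change of -0.84 (camera adjusted p = 9.3e-07; adjusted p = 0.14 with an estimated correlation). Chil3 and Fn1 are also on the reparative macrophage list. The genes that fell included Cd177, a surface protein of neutrophils and some monocytes, at 5.04 ± 0.590 CPM in WT and 0.167 ± 0.136 CPM in KO (SD, n = 3 each; log2 fold change -4.88, or -5.71 without KO replicate 3). Ly6c2, a surface marker of inflammatory monocytes, was low in both groups, at 2.14 ± 0.651 and 0.182 ± 0.194 CPM, and lost its call in 5 of the 6 leave-outs, all but that of KO replicate 3 (adjusted p of up to 0.10). Its log2 fold change was -3.50, or -4.50 without KO replicate 3. In the tissue macrophage list 13 of 24 genes rose and 1 fell when adjusted over the list alone, against 10 and 1 over all genes, with a median of 0.59, or -0.02 with library sizes alone (camera adjusted p = 3.4e-06; adjusted p = 0.14 with an estimated correlation). The list shares 6 genes with the efferocytosis and complement list, C1qa and C1qc among them. The member that fell was Lyve1, a hyaluronan receptor of vessel-associated macrophages, from 23.0 ± 8.68 to 8.98 ± 0.865 CPM. Its call was lost without WT replicate 2 or 3 or KO replicate 1 or 2 (adjusted p of up to 0.094). Adgre1, which encodes the macrophage marker F4/80, was at 489 ± 13.1 and 707 ± 85.9 CPM (adjusted p = 0.061). It was called higher in 6 of 20 alternatives, DESeq2 and the fit without KO replicate 3 among them (adjusted p = 0.0078 and 0.013).

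The pro-inflammatory and reparative macrophage lists did not pass the list test. Of 21 measured pro-inflammatory genes, 2 rose and 1 fell (7 and 4 adjusted over the list alone), with a median log2 fold change of -0.14, a mean of 0.10 and a camera adjusted p of 0.78 in the downward direction. Tnf, an inflammatory cytokine, fell from 72.4 ± 5.95 to 34.2 ± 2.09 CPM (SD, n = 3 each; adjusted p = 0.0030). The chemokine genes Cxcl9 and Ccl5 rose, from 0.223 ± 0.269 to 4.18 ± 0.541 CPM and from 0.352 ± 0.266 to 1.65 ± 0.287 CPM. Cxcl9 lost its call without WT replicate 3 or KO replicate 2 (adjusted p of up to 0.067), and Ccl5 without WT replicate 2 or 3 or KO replicate 1 or 2 (adjusted p of up to 0.17). Their log2 fold changes moved from 4.11 to 5.59 without WT replicate 2 for Cxcl9 and from 2.26 to 3.02 without WT replicate 1 for Ccl5. Il1b was at 286 ± 197 CPM in WT and 128 ± 5.75 CPM in KO (log2 fold change -1.16, adjusted p = 0.13). Il1b was called lower in 4 of 20 alternatives, among them the fit without WT replicate 3 (adjusted p = 0.035). Its log2 fold change was -0.46 without WT replicate 1. Nos2 was under 1 CPM in all libraries. Of 26 measured reparative genes, 2 rose and 4 fell (3 and 5 adjusted over the list alone), with a camera adjusted p of 0.58. The rotation test fry, which does not compare a list with other genes, gave an adjusted p of 0.0026 in the downward direction. Clec10a, a lectin, rose from 17.6 ± 2.84 to 45.1 ± 8.17 CPM. Igf1, a growth factor for muscle, rose from 93.9 ± 30.7 to 225 ± 17.7 CPM. It lost its call without WT replicate 2 or KO replicate 2 (adjusted p of up to 0.061). Cd36, a scavenger receptor, fell from 556 ± 55.5 to 194 ± 30.2 CPM. Arg1, which encodes arginase, was at 94.0 ± 85.0 and 20.7 ± 6.25 CPM (log2 fold change -2.18, adjusted p = 0.052). It was called lower in 8 of 20 alternatives, among them DESeq2 (adjusted p = 0.028), limma-voom (0.011) and the fit without WT replicate 1 (0.042, log2 fold change -1.12), in a range of 1.3e-31 to 0.27. Mrc1, the mannose receptor, was at 752 ± 289 and 837 ± 133 CPM (adjusted p = 0.78).

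Among chemokines and their receptors, 4 of 26 measured genes rose and 8 fell (6 and 12 adjusted over the list alone; camera adjusted p = 0.11, fry adjusted p = 0.035 in the downward direction). The list was called lower without WT replicate 3 (adjusted p = 0.0495) and with no count filter (0.031). Ccl2, the main attractant of monocytes, fell from 210 ± 91.9 to 42.3 ± 5.65 CPM, Ccl6 fell from 198 ± 61.9 to 59.7 ± 5.98 CPM and the receptor Ccr1 fell from 60.5 ± 15.3 to 17.3 ± 0.677 CPM (SD, n = 3 each). Cxcl16 rose from 125 ± 29.7 to 308 ± 7.74 CPM. Of 24 measured NF-kB feedback targets, 6 rose and 4 fell (8 and 9 adjusted over the list alone; camera adjusted p = 0.71). The risers included Nfkb2 and Relb, which encode subunits of the non-canonical branch, at log2 fold changes of 0.90 and 0.97, both of which lost their call without KO replicate 1 or 2 (adjusted p of up to 0.073 and 0.072).

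A difference in genes of lactate handling was not detectable with edgeR. None of the 10 measured genes of lactate transport and sensing changed, over all genes or adjusted over the list alone, where 2 had an unadjusted p under 0.05, DESeq2 called 0 and limma-voom 1. The list's camera adjusted p was 0.58. Slc16a1, the lactate transporter MCT1, was at 22.4 ± 7.55 CPM in WT and 14.6 ± 5.07 CPM in KO (SD, n = 3 each; log2 fold change -0.62, SE 0.31, adjusted p = 0.27). Slc16a1 was called lower with library sizes alone (adjusted p = 0.0062) and with no count filter (0.024). Slc16a7, another monocarboxylate transporter, was at 26.3 ± 5.09 and 33.9 ± 1.19 CPM (adjusted p = 0.21, or 0.015 with limma-voom). In glycolysis 2 of 23 measured genes rose and none fell, over all genes and adjusted over the list alone (camera adjusted p = 0.44, or 0.88 with an estimated correlation of 0.22). In the comparison that rests on KO replicate 3 alone, the list's median was -0.63 with KO replicates 1 and 2 left out and -0.58 with a sex term. Its summed level was 2074 CPM in KO replicate 3 and 3019 to 3647 CPM in the other libraries. The genes that rose were Pfkm, the muscle form of phosphofructokinase, at a log2 fold change of 0.82, and Pfkfb4, an enzyme of the same family as Pfkfb3, at 0.65. Pfkm lost its call in 4 of the 6 leave-outs, those of WT replicates 2 and 3 and KO replicates 1 and 2 (adjusted p of up to 0.13), and Pfkfb4 in all 6 (adjusted p of up to 0.13). In the hypoxia response 2 of 25 genes rose (3 rose and 2 fell adjusted over the list alone; median -0.08, mean 0.01, camera adjusted p = 0.74). Vldlr, a lipoprotein receptor, rose from 0.326 ± 0.0562 to 2.64 ± 0.852 CPM, and Pfkfb4 is on this list too. Hif1a was at 146 ± 10.0 and 111 ± 7.43 CPM (adjusted p = 0.089; called lower in 3 of 20 alternatives). In oxidative phosphorylation 2 of 45 genes fell, over all genes and adjusted over the list alone (camera adjusted p = 0.14, or 0.88 with an estimated correlation of 0.63). At the preset correlation the list was called lower without KO replicate 1 (adjusted p = 0.0059) or 2 (0.033), with these summed (0.014) and with library sizes alone (0.0084). In KO replicate 3 alone the list's median was -0.46 with replicates 1 and 2 left out and -0.41 with a sex term. Its summed level was 2373 CPM in KO replicate 3 and 3073 to 3549 CPM in the other libraries. The genes that fell were the cytochrome oxidase subunits Cox7b, which lost its call without KO replicate 2 (adjusted p of up to 0.059), and Cox6c, which lost it without WT replicate 1 or 2 or KO replicate 1 or 2 (adjusted p of up to 0.13). In the tricarboxylic acid cycle and fatty acid oxidation, edgeR called 0 of 29 genes, over all genes and adjusted over the list alone, 4 had an unadjusted p under 0.05, DESeq2 called 0 and limma-voom 5 higher and 1 lower (camera adjusted p = 0.58). This list too was called lower with library sizes alone, at the preset correlation (camera adjusted p = 0.038). In the main fit its adjusted p was 0.88 with an estimated correlation of 0.46. In KO replicate 3 alone its median was -0.35 with replicates 1 and 2 left out and -0.30 with a sex term.

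Of 29 measured angiogenic and growth factor genes, 5 rose and 2 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.58). Pdgfb, a growth factor that recruits mural cells, rose from 40.8 ± 2.83 to 120 ± 19.9 CPM, and Pdgfc rose from 7.71 ± 0.851 to 18.9 ± 3.41 CPM (SD, n = 3 each). Spp1 and Thbs1, the gene of the angiogenesis inhibitor thrombospondin 1, fell; Thbs1 went from 1099 ± 778 to 243 ± 11.1 CPM and lost its call without KO replicate 1 or 2 (adjusted p of up to 0.090). The log2 fold change of Thbs1 was -2.17, or -1.43 without WT replicate 1. Vegfa was at 46.7 ± 36.9 and 40.0 ± 7.02 CPM (log2 fold change -0.22, adjusted p = 0.82; 0.64 without WT replicate 1, adjusted p = 0.13). In the matrix and protease list, 5 of 32 genes rose and 7 fell (10 and 10 adjusted over the list alone; camera adjusted p = 0.44). Mmp14, a membrane collagenase, rose from 158 ± 35.6 to 376 ± 66.4 CPM and lost its call without WT replicate 2 or KO replicate 1 or 2 (adjusted p of up to 0.069).

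In the efferocytosis and complement list, 6 of 25 measured genes rose and 2 fell (8 and 5 adjusted over the list alone; camera adjusted p = 0.20). C3, the central complement component, rose from 27.5 ± 2.56 to 174 ± 18.4 CPM (SD, n = 3 each; log2 fold change 2.66, SE 0.14, adjusted p = 8.9e-05). Msr1, a scavenger receptor, fell from 333 ± 8.87 to 192 ± 27.5 CPM and lost its call without WT replicate 2 or KO replicate 1 or 2 (adjusted p of up to 0.072). C4b, a complement gene outside the list, rose from 5.54 ± 0.342 to 59.2 ± 12.7 CPM. Of 20 measured genes of iron and haem handling, 5 rose and none fell (7 and 1 adjusted over the list alone), with a median log2 fold change of 0.43, or -0.19 with library sizes alone (camera adjusted p = 0.0059; adjusted p = 0.20 with an estimated correlation). Besides Slc40a1 they included Cp, which encodes the ferroxidase ceruloplasmin, at 1.64 ± 0.443 and 17.3 ± 6.68 CPM. The list was not called in KO replicate 3 alone, a single sample (median 0.05, adjusted p = 0.27 with replicates 1 and 2 left out; 0.10, adjusted p = 0.16 with a sex term). Its adjusted p was in a range of 0.00042 to 0.27 over 17 alternatives. In lipid handling 4 of 33 genes rose and 4 fell (7 and 4 adjusted over the list alone; camera adjusted p = 0.66). Pltp, a phospholipid transfer protein, rose from 159 ± 25.3 to 611 ± 126 CPM, and Plin2, a lipid droplet coat protein, fell from 465 ± 70.9 to 209 ± 11.8 CPM.

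Of 35 measured interferon-stimulated genes, 3 rose and none fell (4 and none adjusted over the list alone), with a median log2 fold change of 0.59, or -0.02 with library sizes alone (camera adjusted p = 1.4e-05; adjusted p = 0.83 with an estimated correlation). The list's mean log2 CPM was 5.26, 5.19 and 5.23 in KO replicates 1 to 3 and 2.93, 4.64 and 5.18 in WT replicates 1 to 3. Its median log2 fold change was 0.17 without WT replicate 1 and 1.06 without WT replicate 3. Gbp2, an interferon-induced GTPase, rose from 10.9 ± 3.50 to 32.3 ± 3.82 CPM (SD, n = 3 each). Of 12 measured genes of MHC class II presentation, 2 rose and none fell (5 and none adjusted over the list alone), with a median of 0.60, or -0.01 with library sizes alone (camera adjusted p = 0.0057; adjusted p = 0.83 with an estimated correlation). The list's mean log2 CPM was 7.29, 6.43 and 5.95 in WT replicates 1 to 3 and 7.32 to 7.37 in the KO libraries, and its median was 1.28 without WT replicate 1. The genes that rose were Ciita, the master regulator of class II genes, at 19.0 ± 7.81 and 49.2 ± 12.4 CPM, and H2-Eb1, at 257 ± 155 and 734 ± 99.2 CPM. Ciita lost its call without WT replicate 2 or any KO replicate (adjusted p of up to 0.097), and H2-Eb1 without WT replicate 2 or 3 or KO replicate 1 or 2 (adjusted p of up to 0.14). The log2 fold change of H2-Eb1 was 1.52, or 2.13 without WT replicate 1. The class II list was not called in KO replicate 3 alone, a single sample, where its median was 0.68 with replicates 1 and 2 left out (adjusted p = 0.065) and 0.60 with a sex term (adjusted p = 0.089). Its adjusted p was in a range of 1.1e-07 to 0.089 over 17 alternatives.

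Of 41 measured cell cycle genes, 1 fell and none rose, over all genes and adjusted over the list alone, with a median log2 fold change of -0.21 (camera adjusted p = 0.049; adjusted p = 0.88 with an estimated correlation). It was Mki67, a proliferation marker, which went from 378 ± 51.1 to 193 ± 33.8 CPM (SD, n = 3 each) and lost its call without WT replicate 2 or KO replicate 1 or 2 (adjusted p of up to 0.072). The list's mean log2 CPM was 5.16 and 5.10 in KO replicates 1 and 2, 4.07 in KO replicate 3 and 4.65 to 5.36 in the WT libraries. The list was not called without WT replicate 2, WT replicate 3 or KO replicate 3, with adjusted p-values of up to 0.40, and its median was 0.06 without WT replicate 3 and 0.09 without KO replicate 3. It was kept in 9 of 17 alternatives.

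Markers of other cell types moved in different directions in the same libraries. Of 22 measured skeletal muscle fibre genes, 15 rose and none fell, over all genes and adjusted over the list alone (median log2 fold change 2.03, camera adjusted p = 3.1e-11; adjusted p = 0.14 with an estimated correlation). Acta1, skeletal muscle actin, rose from 3.98 ± 1.02 to 24.5 ± 4.50 CPM and Myl1, a myosin light chain, from 0.615 ± 0.185 to 8.05 ± 2.09 CPM (SD, n = 3 each). Of 10 satellite cell and myoblast genes, 5 rose (6 adjusted over the list alone; median 2.43, camera adjusted p = 1.3e-08; adjusted p = 0.14 with an estimated correlation), among them Vcam1 and Myh3, embryonic myosin, at no more than 0.521 CPM in the WT libraries and at 10.6 CPM or more in the KO libraries. H19, an imprinted RNA abundant in embryonic tissue and muscle precursors, rose from 1.79 ± 0.791 to 83.1 ± 21.0 CPM, and Tnnt2, a troponin of heart and immature skeletal muscle, was at 0.0914 ± 0.158 and 6.53 ± 1.40 CPM, with counts in WT replicate 2 alone of the WT libraries. Of 20 fibroblast and fibro-adipogenic progenitor genes, 11 rose and none fell (15 and 1 adjusted over the list alone; median 1.95, camera adjusted p = 6.1e-10; adjusted p = 0.20 with an estimated correlation). Its median was 2.54 without WT replicate 3. Postn, a matrix protein of fibroblasts, rose from 0.962 ± 0.397 to 13.1 ± 2.01 CPM.

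Endothelial genes went the other way. Of 24 measured, 9 fell and none rose (16 fell adjusted over the list alone; median log2 fold change -1.85, camera adjusted p = 5.3e-10; adjusted p = 0.25 with an estimated correlation). Robo4, an endothelial guidance receptor, fell from 1.65 ± 0.821 to 0.0808 ± 0.0226 CPM, and Flt1, the VEGF receptor 1, from 14.0 ± 8.38 to 2.96 ± 0.842 CPM (SD, n = 3 each). Robo4 lost its call without KO replicate 2 (adjusted p of up to 0.052), and Flt1 without KO replicate 1 or 2 (adjusted p of up to 0.069). The log2 fold change of Flt1 was -2.24, or -1.64 without WT replicate 1. Of 9 measured neutrophil genes, 3 fell and 1 rose (5 and 1 adjusted over the list alone; median -1.92, camera adjusted p = 0.0065; adjusted p = 0.20 with an estimated correlation). The list was not called with library sizes alone (adjusted p = 0.27), and its median was -1.28 without WT replicate 1. Cd177 fell, and Mmp9, a gelatinase, was called higher but overlapped between groups, at 268, 162 and 18.9 CPM in KO replicates 1 to 3 and 14.6, 13.7 and 25.1 CPM in the WT libraries. Its call was lost in all leave-outs except that of KO replicate 3 (adjusted p of up to 0.15). Its log2 fold change was 3.07, or 2.34 without KO replicate 1. The T and NK cell list had 7 measured genes, of which Cd4 alone changed (1 higher and 1 lower adjusted over the list alone; median -0.31, mean 0.17, camera adjusted p = 0.60 in the downward direction). Cd4, a receptor of helper T cells and of some macrophages, rose from 2.49 ± 1.16 to 53.3 ± 9.83 CPM, and Lag3, a receptor that binds MHC class II, rose from 0.991 ± 0.772 to 16.3 ± 3.15 CPM (log2 fold change 4.01, or 4.87 without WT replicate 2). In the dendritic cell list 1 of 18 genes rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.077, or 0.0022 without WT replicate 1 and 0.0053 with library sizes alone), the latter being Cd24a, from 64.1 ± 41.5 to 6.81 ± 1.05 CPM (log2 fold change -3.23, or -2.57 without WT replicate 1). Of 8 measured pericyte and smooth muscle genes 1 rose (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.58).

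**Figure D3:**
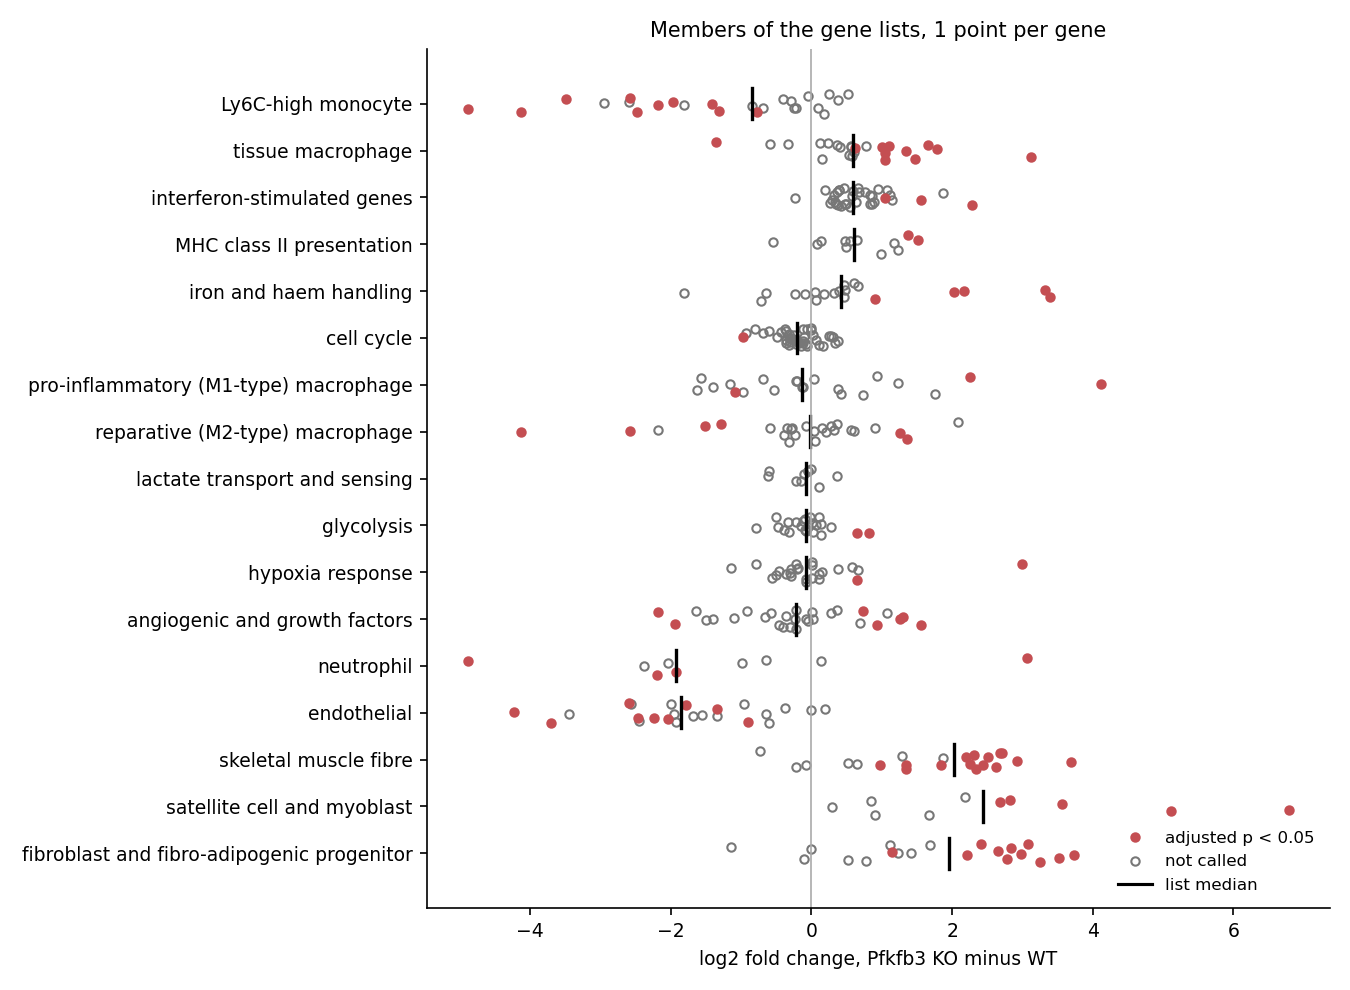
Each point is the log2 fold change of 1 gene (KO minus WT), filled red where the adjusted p was under 0.05, and each vertical line is the median of a list. The medians of the muscle fibre, myoblast and fibroblast lists lie at 1.95 to 2.43 and those of the endothelial and neutrophil lists at -1.85 and -1.92 (neutrophil -1.28 without WT replicate 1). With library sizes alone, which shifts the median of all genes to -0.60, the medians of the tissue macrophage, interferon, MHC class II and iron lists lie below 0. Relative to other genes, these lists still passed the list test upward in that setting (camera at the preset correlation, adjusted p of 1.6e-13 to 0.0041). At that correlation 7 of the 10 splits of the libraries gave as many lists as the real split. With an estimated correlation in the main fit, the camera adjusted p of these lists was 0.14, 0.83, 0.83 and 0.20, in the order named.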

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

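The alternatives with protein-coding genes alone, equal protein-coding totals, the GC and length trend, a sex term, and KO replicates 1 and 2 left out or summed were chosen after seeing the data. The reported count is 995 changed genes, 658 higher and 337 lower in KO, and 11 lists. DESeq2 size factors, the stricter filter, protein-coding genes alone, equal protein-coding totals and the GC and length trend gave 786 to 1201 genes. Library size alone gave 6308 genes (300 higher, 6008 lower), and the median log2 fold change of all genes was then -0.60. No count filter gave 1957 (1034 and 923) over 32474 genes tested, DESeq2 1870 (1092 and 778), and limma-voom 4850 (2601 and 2249). The test against a fold of 1.5 gave 180 (149 and 31), which its stricter null explains in part. With a sex term there were 1495 (794 and 701), with KO replicates 1 and 2 left out 149 (101 and 48), and with both summed 282 (220 and 62); the first 2 rest on KO replicate 3 alone, and the last 2 have fewer samples. With the title ending as a replicate block there were 267 genes (206 and 61). The leave-outs gave 189 (without KO replicate 2) to 1652 genes (without KO replicate 3), with 154 to 963 higher and 35 to 689 lower. Lists numbered 10 to 15 in the alternatives that refit the genes and 10 with fry, and 0 with an estimated correlation. Of the 11 reported lists, fry kept 8. The interferon, MHC class II and cell cycle lists were not called with fry (adjusted p = 0.42, 0.31 and 0.78). No called gene was called in the opposite direction under any of the alternatives. For changes other than those from fewer samples or a stricter null, the cause was not tested.

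Of 1495 values of called named genes under alternatives, 1492 had the same direction and 1173 were still called. The 3 reversals were Rps14 with library size alone (-0.056, against 0.56), Xist with a sex term (-0.82) and Xist with KO replicates 1 and 2 left out (-0.95), the last 2 because these take out the libraries with high Xist. Pfkfb3, not called, was called lower with limma-voom (-0.65); the cause was not tested. Over the leave-outs the cell cycle list's median ranged from -0.46 without KO replicate 1 to 0.087 without KO replicate 3, and the lowest over all alternatives was -1.16, with KO replicates 1 and 2 left out. The ribosomal protein list, not called at 0.02, was called lower in KO replicate 3 alone (-0.22 with a sex term, -0.28 with KO replicates 1 and 2 left out, the same single sample) and higher without that library (0.14, adjusted p = 0.023). Alternatives on a pseudocount did not apply, since the values are counts. Depth limits low genes most in KO, where protein-coding counts were lower.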

Other observations

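Tests of the source of KO replicates 1 and 2, of the muscle transcripts and of the histocompatibility genes were chosen only after the result was seen.

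Of 12 tested genes of MHC class I, which presents peptides to cytotoxic T cells, edgeR called 9 higher and 0 lower in KO; this set was chosen after its values were seen and is not independent evidence of a direction. H2-K1 rose from 456 ± 1.78 to 1271 ± 228 CPM (SD, n = 3 each), and H2-D1 was at 852 to 930 CPM in the WT libraries and at 1560 to 2172 CPM in the KO libraries (log2 fold change 1.14, edgeR adjusted p = 0.010). H2-Q7, a non-classical member, rose from 5.81 ± 0.964 to 48.7 ± 9.40 CPM, and H2-T23 from 50.1 ± 2.58 to 117 ± 12.3 CPM. Tapbp, which loads peptides onto class I, rose from 137 ± 5.79 to 280 ± 68.6 CPM. B2m, the shared light chain, was at 531 ± 88.1 and 627 ± 87.8 CPM (edgeR adjusted p = 0.45), and Tap1, a peptide transporter, at 58.4 ± 16.2 and 107 ± 22.9 CPM (edgeR adjusted p = 0.061).

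Of the integrated stress response list 2 of 24 genes rose and 1 fell (3 and 3 adjusted over the list alone, camera adjusted p = 0.098, or 0.83 with an estimated correlation of 0.20). At the preset correlation the list was called lower without KO replicate 1 (adjusted p = 0.017), with KO replicates 1 and 2 summed (0.036) and with the GC and length trend removed (0.039). Its mean log2 CPM was 4.38 in KO replicate 3 and 4.90 to 5.11 in the other libraries. Of the tissue dissociation list 1 of 24 rose and 2 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.60), and of 48 ribosomal protein genes 2 rose, by both counts (camera adjusted p = 0.66). Of 18 oxidative stress genes edgeR called 0, also adjusted over the list alone, with 3 at an unadjusted p under 0.05, DESeq2 called 1 lower and limma-voom 4 higher and 1 lower (camera adjusted p = 0.60; called lower in the single library KO replicate 3, at 0.018 with replicates 1 and 2 left out and 0.017 with a sex term). Of 5 sex-linked genes Xist was called (1 adjusted over the list alone; median -1.37, mean 0.62, camera adjusted p = 0.17 in the downward direction, or 0.0045 without KO replicate 3). The B cell list had 4 measured genes, of which 1 rose (4 adjusted over the list alone), namely Ighm, from 23.6 ± 2.93 to 60.9 ± 6.90 CPM (SD, n = 3 each). Of 2 erythroid and platelet genes edgeR called 0 (1 lower adjusted over the list alone; 1 at an unadjusted p under 0.05, DESeq2 0, limma-voom 1). Of 4 mast cell and eosinophil genes it called 0 by either count (0 at an unadjusted p under 0.05, DESeq2 0, limma-voom 1). Of 18 tested rows whose symbols had become dates, 1 was called, at a log2 fold change of -0.52 (edgeR adjusted p = 0.033).

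In the count of changed genes, the real split gave 995 genes with edgeR and 1 of the 10 splits of the 6 libraries, the real one, gave as many; the highest of the other splits gave 0, with 114 to 1141 genes at an unadjusted p under 0.05 against 3516. For lists the real split gave 11 at the preset correlation of 0.01, and 7 of the 10 splits gave as many. The other splits gave 8 to 16 lists, while edgeR called 0 genes in each of them. Passing the list test at the preset correlation therefore does not set the genotype split apart from other splits. The estimated correlation of a list reached 0.89, and 0 lists passed with estimated correlations. Where the correlation within a list is far above the preset value, the test is liberal. Whether a structure of the samples also played a part was not tested. For genes and lists alike, 10 splits are too few for a share under 0.05. Genes called between KO replicates 1 and 2 and 2 WT libraries had the same sign between KO replicate 3, of the other sex type, and the WT library left out in 77.9%, 94.0% and 76.8% of cases without WT replicate 1, 2 and 3, against about 50% by chance, which argues against sex as the whole cause. Removing the GC and length trend left 67.6% of 987 genes called, and the 320 that lost the call went from a median size of 0.74 to 0.58 with SEs of 0.162 and 0.169, so a part played by GC content or length stays open. With KO replicates 1 and 2 summed, 282 genes passed. This number depends on the number of samples and cannot tell whether both came from 1 source. The low chi-square between them and their shared high Xist would go with 1 source but do not show it, so the question stays open. A part played by the genotype itself stays open too, since the design does not separate it from other differences between the groups.

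In the rise of muscle transcripts, not every other cell type rose alike, since the median of the endothelial list was -1.85. This fall was known when the test was chosen. As the deletion was taken to be endothelial, the list could also change with the genotype itself. A lower share of macrophages with more RNA of muscle and fibroblasts therefore stays open. RNA of regenerating muscle, carried over through the sort for macrophages or taken up by them, may be a source: Myh3, Myh8 and Myog had a median log2 fold change of 5.11, and these genes were among those seen to rise. Of the most abundant fibre genes, Acta1 was at 20.6 to 29.4 CPM in the KO libraries and Ckm at no more than 3.87 CPM. Carried-over RNA and uptake by macrophages cannot be told apart, since the libraries are bulk RNA with no measure of where it was. A difference in the state of the muscle between genotypes also stays open, untested.

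In the higher levels of histocompatibility genes, a carried H-2k haplotype in the KO libraries is argued against by H2-Ea-ps, at 0% of the H2-Eb1 count in all 3 (0 counts, which allows up to 0.0312%, for counting error only). Reads only moved between class I paralogs are argued against by the summed CPM of 16 class I genes, which was 2.41 times as high in KO. The sum was 1515 ± 10.5 CPM in WT and 3652 ± 585 CPM in KO (SD, n = 3 each, exact two-sided permutation p = 0.1, the smallest possible). It was 1504 to 1525 CPM in the WT and 2978 to 4028 CPM in the KO libraries, and 1.57 times as high in KO with library sizes alone. A difference in how many class I reads were counted at all stays open, since the counting settings are not given. Other genes between 33 and 39 Mb of chromosome 17 were called at 0.81 times the share of all tested genes (6 of 112; odds ratio 0.81, 95% confidence interval 0.29 to 1.83), against 17 of 33 immune genes there. A differing segment stays open, since the interval reaches above the 1.5 set as the bound and a segment could act through the immune genes alone, and so does a response of the macrophages to the genotype, untested.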
